A study of Pimephales promelas with 11 samples.

How the data were processed

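Livers of 11 female fathead minnows were analysed, 1 array per fish, and per the labels each fish is a separate animal. Per the labels the fish of a group came from tanks with different numbers (4 to 6), and p-values measure the spread between these fish. Per the file headers, the arrays were one-colour Cy3 Agilent arrays read with Feature Extraction 10.7.3.1, while the submitters' processing notes name version 9.5. The deposited scanner files hold intensity values: the processed signal, which per the file headers is background-subtracted within the array and not normalized between arrays, and the mean and background brightness of each spot. The series also holds a deposited table of log2 values. Per the series' design text it was normalized with Fastlo, and its log base, centring and background treatment are not given in the sources used here.

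Each column of that table was set against the same array's scanner values. It followed the log2 spot mean with r between 0.991 and 1.000. The table's medians were 6.29, 6.31 and 6.28 for the controls (replicates 2, 4 and 5), 6.61, 6.61 and 6.61 for 1 ng/L, 6.23 and 6.22 for 10 ng/L, and 6.53, 6.72 and 6.57 for 100 ng/L. The median absolute distance of a column from a fast cyclic loess run within its own group was 0.00241 to 0.0418, and from one run over all 11 arrays 0.0825 to 0.337. The table's scale (log2 of the spot mean) was therefore taken from the values, its direction is that of brightness, and the authors' exact centring stays unknown. The table was used only as an alternative.

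The main values were log2 of the processed signal of the 15208 non-control probes, normalized over all 11 arrays with limma's fast cyclic loess (limma 3.58.1 in R 4.3.3), which follows the method named in the design text. Outlier-flagged spots were set to missing after normalization, and saturated spots were kept. Probes well above background on at least 2 arrays were tested, which left 12571. One mean per group was fitted to all 11 arrays with lmFit and eBayes, so that groups shared one estimate of the spread (7 residual and 3.06 prior degrees of freedom). Contrasts of each concentration with the control and between concentrations, an F-test over the 3 contrasts with the control and a slope on log10(concentration + 1) were tested. Probes with a Benjamini-Hochberg adjusted p under 0.05 within a contrast were called. The fits were tested on simulated data with 200 changed probes among 12571. At a log2 change of 2 they recovered 23 of 67 changed probes for 1 ng/L against control, 9 of 67 for 10 ng/L and 17 of 67 for 100 ng/L. At a change of 3 they recovered 36 of 66, 34 of 66 and 38 of 66, and at a change of 1 they recovered 0 of 67 in each.

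Signal varied between arrays. The 75th percentile of the processed signal was 97.1 on DES 10 ng/L replicate 3 and 103 on DES 100 ng/L replicate 1, and 239 to 612 on the other arrays. The 11 arrays lay on 3 slides scanned on the same day. Slide 1 held 1 control and 1 array of 100 ng/L, slide 2 held 1 control, 1 array each of 1 and 10 ng/L and 2 arrays of 100 ng/L, and slide 3 held 1 control, 2 arrays of 1 ng/L and 1 of 10 ng/L. DES 100 ng/L replicate 4 had 163 outlier-flagged spots, and the other arrays had at most 11. Spike-in signal was the mean log2 processed signal of the 4 of 10 spike-in control probes that were well above background and unsaturated on all arrays. Arrays of the same group correlated with r between 0.916 and 0.954 across probes, and arrays of different groups with r between 0.864 and 0.945, so none was a duplicate of another.

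No probe was tied to a gene with the names used here. Every probe shared 1 placeholder description, and 0 of 15208 contig or sequence identifiers matched the table of RefSeq genes of this species that was used for names. The 31 gene lists fixed before the data were examined, 7 of them marker lists of other cell types, and the comparison of the array signal of vtg and esr1 with the labels' values were therefore not run. The rule for named genes required a gene name and so selected 0 probes. The 2 largest rises and 2 largest falls at 100 ng/L among called probes whose treated and control arrays did not overlap are reported instead by probe and contig identifier, a choice made after the probes were seen to carry no gene name.

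Fish endpoints were copied from the labels. The labels give no unit for plasma vitellogenin and no unit or method for the liver mRNA values. Each concentration was compared with the control by an exact two-sided permutation test of the difference in means, on log10 values for mRNA and steroids and on linear values for the gonadosomatic index, plasma vitellogenin and weight, in 23 tests (ex vivo oestradiol at 10 ng/L had 1 value and no test). Trends used Pearson's r and Spearman's rho with 100000 resamples, or all orders for 9 or fewer fish, in Python 3.11.15 with NumPy 2.4.6. Comparisons with shared controls were set beside 100 simulated sets of unchanged groups.

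The alternatives were 75th percentile scaling, quantile normalization, normexp background correction with an offset of 50, no filter and a filter on all 11 arrays, outlier-flagged spots kept, the deposited table, replicate blocks by tank number and by the fish number in the title, the slide as a block, an intensity trend with robust prior, array weights, only the 2 groups compared, each array left out, and for endpoints the other scale and the rank of concentration. Arrays were left out of the fit and not of the normalization. After the data had been seen, the spot mean without background subtraction, the table normalized again over all arrays, the spike-in level as a block, and fits without the 2 dimmest arrays were added. Separate controls for 2 comparisons, slopes on endpoints without other sets of 3 fish, and regroupings of arrays within slides were also added then.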

Results

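The livers of 11 adult female fathead minnows (Pimephales promelas, a small freshwater fish used in toxicity testing) were profiled with one-colour 60-base oligonucleotide arrays. Treated fish had been kept for 96 h in water with 1, 10 or 100 ng/L diethylstilbestrol (DES), a synthetic oestrogen, and then for a further 96 h in clean water. Per the labels the controls had 0 h of exposure and 96 h of recovery. The arrays therefore describe the recovery phase, and the comparisons ask which liver transcripts still differed from the control after that time at each concentration. The control, 1 ng/L and 100 ng/L groups held 3 fish each and the 10 ng/L group held 2. The labels also gave the levels of 2 liver transcripts in each fish, vtg (vitellogenin, the egg yolk precursor made by the liver under oestrogen) and esr1 (oestrogen receptor alpha), together with plasma vitellogenin, the gonadosomatic index and steroid concentrations. Of 15208 probes, between 7801 and 13592 were well above background on an array, and 12571 were tested. The fewest were found on DES 10 ng/L replicate 3 and the most on DES 100 ng/L replicate 4. The number of arrays limits the precision of every value given here.

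After recovery from 100 ng/L, liver vtg mRNA was 75.3-fold below the control mean and liver esr1 mRNA was 5.48-fold below it, while plasma vitellogenin was 4.59 times the control mean. Liver vtg mRNA averaged 85100 ± 15704 (SD, n = 3) against 6410000 ± 1578480 (SD, n = 3) in the controls, in the labels' values, whose unit and method are not given there. Liver esr1 mRNA averaged 57.8 ± 5.64 (SD, n = 3) against 317 ± 53.5 (SD, n = 3) on the same terms. Plasma vitellogenin averaged 53.8 ± 6.84 (SD, n = 3) against 11.7 ± 5.56 (SD, n = 3), again with no unit in the labels. The gonadosomatic index, the gonad's share of body weight, averaged 2.45% ± 1.14 (SD, n = 3) against 9.92% ± 3.19 (SD, n = 3). Ex vivo testosterone production, for which the labels name no tissue, averaged 0.0313 ± 0.0271 ng/mL per 12 h (SD, n = 3) against 0.110 ± 0.0172 (SD, n = 3). For each of these 5 endpoints all 3 fish of the 100 ng/L group lay on one side of all 3 controls, and the exact two-sided permutation test gave p = 0.1, the smallest that 3 fish against 3 allow (adjusted p = 0.23 over 23 tests). The labels give tanks numbered 4, 5 and 6 in both groups, and within each of these 3 numbers vtg mRNA at 100 ng/L was between 0.0104 and 0.0168 times the control's, and esr1 mRNA between 0.151 and 0.240 times. Since the groups do not overlap, any pairing of these fish puts the treated fish below its control, so the tank numbers add no separate evidence.

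**Figure D1:**
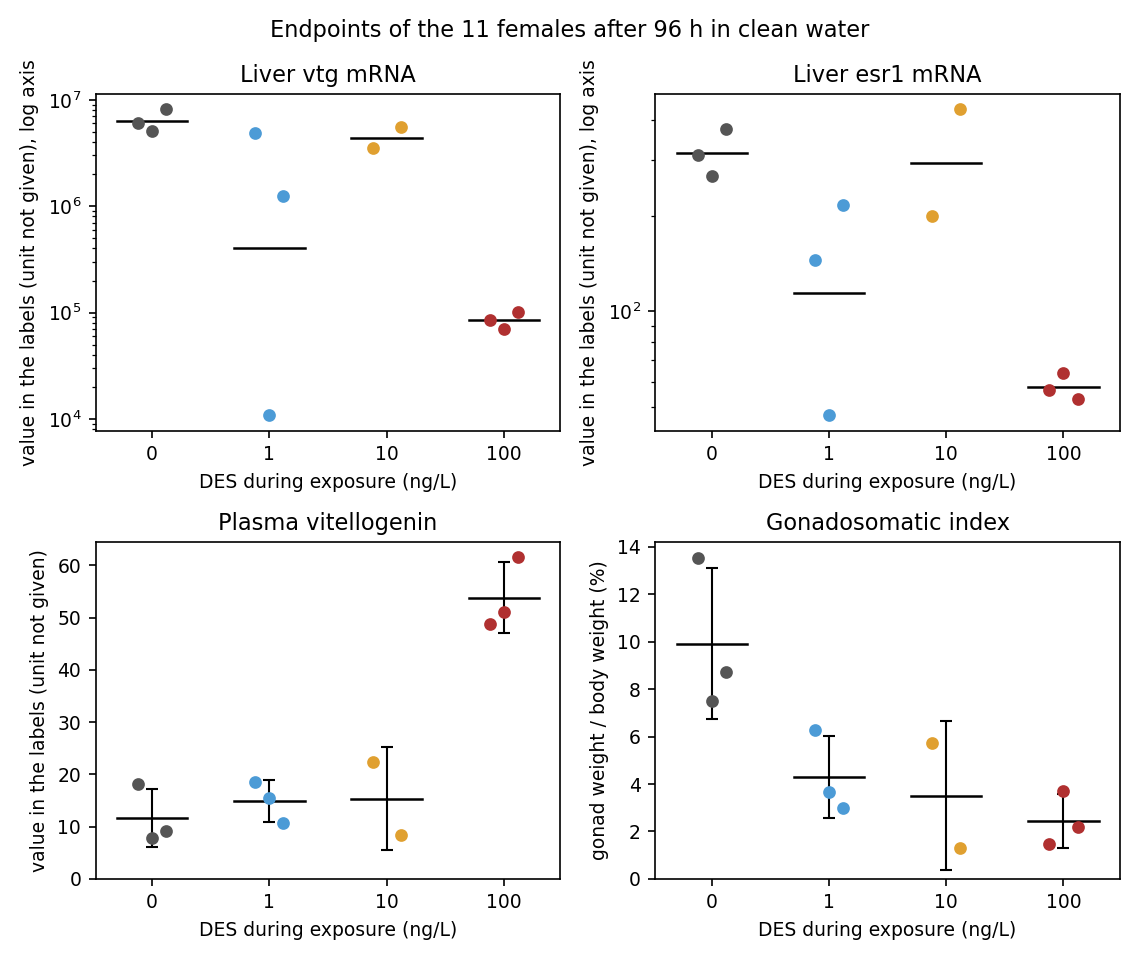
Each point is one female after 96 h in clean water, plotted against the DES concentration of the preceding exposure (ng/L); liver vtg and esr1 mRNA are on log axes with lines at the geometric means, and plasma vitellogenin and gonadosomatic index (%) are on linear axes with lines at the means and SD bars. At 100 ng/L vtg mRNA lay between 69600 and 101000 and every control was at 5070000 or more, while plasma vitellogenin lay between 48.8 and 61.6 and every control was at 18.1 or less.

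The lower concentrations did not follow an even order between control and 100 ng/L. At 1 ng/L liver vtg mRNA ranged from 10800 to 4900000, so that 1 fish (DES 1 ng/L replicate 4) lay below the 100 ng/L group and 1 lay close to the controls. Liver esr1 mRNA at 1 ng/L averaged 136 ± 84.5 (SD, n = 3), and all 3 fish were below all controls in both transcripts (exact permutation p = 0.1 each, the smallest possible; adjusted p = 0.23). At 10 ng/L the fish had 3490000 and 5560000 for vtg mRNA and 199 and 432 for esr1 mRNA, against a lowest control of 5070000 and 267. The exact permutation p at 10 ng/L was 0.3 for vtg mRNA and 0.9 for esr1 mRNA. Plasma vitellogenin averaged 14.9 ± 3.93 (SD, n = 3) at 1 ng/L and 15.3 ± 9.86 (SD, n = 2) at 10 ng/L, and the difference from the control was not larger than the spread between fish (exact permutation p = 0.4 and 0.6). The gonadosomatic index averaged 4.31% ± 1.73 (SD, n = 3) at 1 ng/L and 3.50% ± 3.13 (SD, n = 2) at 10 ng/L, and all 5 fish were below all controls (exact permutation p = 0.1 for each group, the smallest possible; adjusted p = 0.23). Ex vivo testosterone at 10 ng/L averaged 0.0659 ± 0.0219 ng/mL per 12 h (SD, n = 2), with both fish below all controls (exact permutation p = 0.1, adjusted p = 0.23). At 1 ng/L it averaged 0.102 ± 0.0735 (SD, n = 3), with 2 fish below and 1 above all controls (exact permutation p = 0.6).

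Over all concentrations, plasma vitellogenin increased with log10(concentration + 1) (Pearson's r = 0.890, permutation p = 0.00155, adjusted p = 0.0124 over 8 endpoints; Spearman's rho = 0.740, permutation p = 0.0121; 11 fish). Ex vivo testosterone fell with concentration (r = -0.715, permutation p = 0.00456, adjusted p = 0.0182; rho = -0.745, permutation p = 0.0112; 11 fish). The adjusted p of Pearson's r was 0.0613 for the gonadosomatic index (r = -0.665), 0.0846 for esr1 mRNA (r = -0.629) and 0.111 for vtg mRNA (r = -0.563), all by permutation. The adjusted permutation p of Spearman's rho was 0.0322 for the gonadosomatic index (rho = -0.759), 0.126 for esr1 mRNA (rho = -0.558) and 0.0637 for vtg mRNA (rho = -0.661). Without DES 1 ng/L replicate 4 the permutation test gave r = -0.889 (adjusted p = 0.00776) for vtg mRNA, r = -0.824 (adjusted p = 0.0112) for esr1 mRNA and adjusted p = 0.0315 for the gonadosomatic index. Leaving out DES 1 ng/L replicate 6 gave a permutation adjusted p of 0.0369 for the index, and leaving out DES 100 ng/L replicate 4 or 5 took ex vivo testosterone to 0.0644 or 0.129. The 2 fish farthest from the median concentration were any pair of the 100 ng/L group. Without such a pair, r was 0.792 to 0.807 for plasma vitellogenin (exact permutation p = 0.0278), -0.844 to -0.498 for testosterone (0.0131 to 0.175) and -0.668 to -0.550 for the gonadosomatic index (0.0490 to 0.131), so the last 2 relations rested on those fish for some pairs. For esr1 mRNA r was then -0.430 to -0.384, and for vtg mRNA -0.377 to -0.342. Without all 3 fish of that group r was 0.246 for plasma vitellogenin (exact permutation p = 0.516, n = 8) and -0.468 for testosterone (exact permutation p = 0.248, n = 8), so both calls were lost with 8 fish. It was -0.630 for the gonadosomatic index (exact permutation p = 0.0964, n = 8), 0.0613 for esr1 mRNA and 0.0178 for vtg mRNA. Plasma oestradiol (r = -0.449, n = 11), ex vivo oestradiol (r = 0.141, n = 9) and body weight (r = 0.227, n = 11) showed no relation past the threshold, with permutation adjusted p of 0.223, 0.736 and 0.569.

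The question for the arrays at 100 ng/L was which liver transcripts differed after recovery. Compared with the control, 981 probes were called by limma at an adjusted p under 0.05, 418 of them higher and 563 lower. The change was over 4-fold for 495 of them, 197 higher and 298 lower, and above 16-fold for 14 of the higher and 40 of the lower. These sizes come from the background-subtracted signal and were not counted under other background treatments. In that signal 365 probes (DES 100 ng/L replicate 4) to 4003 (DES 10 ng/L replicate 3) per array carried a surrogate value in place of a measured one. The size of falls that end near background can thus be overstated. In 973 of the 981 the 3 treated arrays did not overlap the 3 controls, and over all tested probes this held for 31.4%, where chance gives 10%. The 2 largest falls and the 2 largest rises by the processed signal among the called probes whose groups did not overlap are given by probe and contig identifier, since the files pair neither with a gene. Probe UF_Ppr_AF_107820 (contig FJU.14120.C1, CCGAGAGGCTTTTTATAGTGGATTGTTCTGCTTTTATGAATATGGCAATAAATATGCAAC) fell by 6.93 ± 1.32 on the log2 scale (SE, limma adjusted p = 0.0165). Its normalized log2 signal was 9.83 ± 0.37 (SD, n = 3) in the controls and 2.90 ± 1.95 (SD, n = 3) at 100 ng/L, where 1 of 3 arrays was well above background. The size and rank of this fall depend on the background treatment, and the log2 change was -3.46 with normexp, -3.74 with the spot mean (an alternative chosen after seeing the data) and -3.61 in the authors' deposited values. Probe UF_Ppr_AF_105439 (contig FJU.975.C1, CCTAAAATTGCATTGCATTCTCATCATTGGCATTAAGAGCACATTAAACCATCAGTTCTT) fell by 6.78 ± 0.96 (SE, limma adjusted p = 0.00818), from 11.76 ± 0.10 (SD, n = 3) to 4.98 ± 0.32 (SD, n = 3). It was well above background on all of these arrays and had a log2 change of -5.05 with normexp. Probe UF_Ppr_AF_104891 (contig FJU.927.C1, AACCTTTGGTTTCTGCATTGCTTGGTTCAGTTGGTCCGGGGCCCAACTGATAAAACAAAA) rose by 8.38 ± 1.53 (SE, limma adjusted p = 0.0139), from 6.21 ± 2.19 (SD, n = 3), with 2 of 3 controls well above background, to 14.58 ± 2.21 (SD, n = 3). Probe UF_Ppr_AF_112224 (contig FJU.711.C3, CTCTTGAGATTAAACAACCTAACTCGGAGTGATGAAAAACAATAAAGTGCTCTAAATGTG) rose by 6.54 ± 0.89 (SE, limma adjusted p = 0.00818), from 9.28 ± 0.61 (SD, n = 3) to 15.81 ± 0.18 (SD, n = 3), with 2 of 3 spots saturated at 100 ng/L, where the signal is a lower limit. With normexp the log2 change of UF_Ppr_AF_104891 was 7.26, and in the authors' deposited values it was 7.10. The call of UF_Ppr_AF_107820 was lost without control replicate 4 (limma adjusted p = 0.0639), control replicate 5 (0.0527) or DES 100 ng/L replicate 5 (0.0586), and with the slide as a block (0.0508), and that of UF_Ppr_AF_104891 without DES 100 ng/L replicate 5 (0.0567). With the spike-in level as a block all 4 missed the threshold (limma adjusted p = 0.0552 to 0.109). That block leaves DES 100 ng/L replicate 1 alone against the controls, since it is the only array of its group at their spike-in level. The log2 changes of that array were -6.27 ± 1.94 (SE) for UF_Ppr_AF_107820, -6.49 ± 1.42 (SE) for UF_Ppr_AF_105439, 9.94 ± 2.16 (SE) for UF_Ppr_AF_104891 and 6.73 ± 1.33 (SE) for UF_Ppr_AF_112224. Over all settings adjusted p lay between 0.000723 and 0.109.

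In the called direction, the median change at 100 ng/L of the 981 probes, which were selected on these same arrays, was 2.02 on the log2 scale without a block and 1.98 with the slide as a block, which called 448 probes. Of the 2 slides with both groups, it was 2.05 on the slide that held 1 control and 1 array of 100 ng/L, and 2.15 on the slide that held 1 control and 2 such arrays. Spike-in control RNA read 10.26 to 10.62 (mean log2 processed signal of 4 probes) on the control arrays and 11.21 on DES 100 ng/L replicate 1, but 8.45 and 8.52 on the other arrays of that group. With the spike-in level as a block, DES 100 ng/L replicate 1 alone is set against the controls. The median change of the 981 probes was then 2.09, and the median SE over all probes rose from 0.52 to 0.69. Without the 2 dimmest arrays, an alternative chosen after seeing the data like that block, 345 probes were called. Leaving out 1 array gave 442 without control replicate 2, 114 without control replicate 4, 385 without control replicate 5, 442 without DES 100 ng/L replicate 1 and 237 without DES 100 ng/L replicate 5. Scaling each array to its 75th percentile called 584 higher and 500 lower, and under it the median of all probes lay 0.39 above the control, against 0.07 with cyclic loess.

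**Figure D2:**
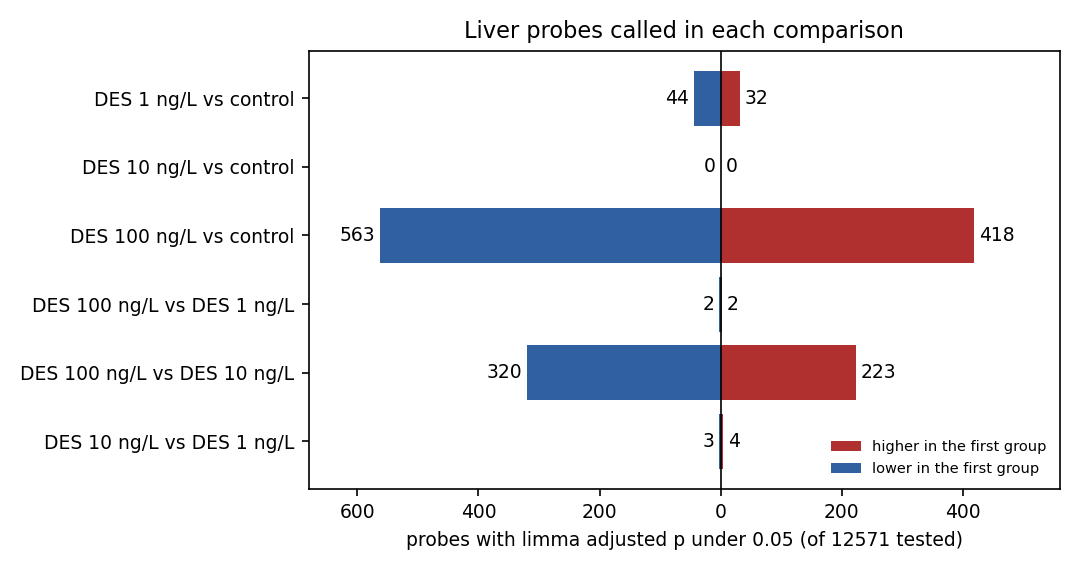
Bars give the number of liver probes with a limma adjusted p under 0.05, of 12571 tested, that were higher (right) or lower (left) in the first-named group of each comparison. The comparisons of 100 ng/L with control (418 and 563) and with 10 ng/L (223 and 320) hold most of the calls, and 10 ng/L against control holds 0.

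At 1 ng/L the liver differed from the control in 76 probes by limma, 32 higher and 44 lower, with a median size of 2.55 on the log2 scale. The change exceeded 4-fold in 28 of the higher and 36 of the lower, by the same background-subtracted signal. Probe UF_Ppr_AF_107820 was among them and was called lower (limma adjusted p = 0.0475), with 1 of 3 arrays of 1 ng/L well above background. The log2 changes of UF_Ppr_AF_105439 (-4.44 ± 0.96, SE), UF_Ppr_AF_112224 (3.63 ± 0.89, SE) and UF_Ppr_AF_104891 (1.45 ± 1.53, SE) had limma adjusted p of 0.0690, 0.0938 and 0.650. Of the 76 probes, 24 were also called higher and 39 also called lower at 100 ng/L, where independent lists of these sizes would share 1.06 and 1.97. The 981 probes called at 100 ng/L had the same sign at 1 ng/L in 99.0% and at 10 ng/L in 65.0%. In unchanged groups simulated against the same controls, the 981 probes with the largest t at 100 ng/L gave 86.5% and 83.0%. In that simulation the 100 ng/L group was unchanged too, so its probes were picked on spread alone, part of it from the shared controls. The simulated shares are thus no benchmark for probes that did change at 100 ng/L. At 1 ng/L the 981 called probes had a median of 1.02 for the higher and -1.31 for the lower ones. All 12571 probes together gave r = 0.684 between the 2 sets of log2 changes, and unchanged groups simulated against the same controls gave 0.498. The covariance was 0.784 against 0.243 in the simulation, a difference of 0.541. Part of the excess overlap in calls may come from the shared controls, and no split of 3 controls leaves 2 on each side. With 1 control for one comparison and the other 2 for the other, in all 6 ways, chosen after seeing the data, r was 0.317 to 0.511 and the covariance 0.479 to 0.693. In these splits the 2 comparisons share no control, so shared controls are argued against as the whole source of the covariance.

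The count at 1 ng/L was unstable. Without control replicates 2, 4 and 5 in turn it was 11, 2 and 4, without DES 1 ng/L replicates 3, 4 and 6 it was 17, 9 and 155, without either array of 10 ng/L it was 22, and without DES 100 ng/L replicates 1, 4 and 5 it was 17, 9 and 7. It was 0 with the spike-in level as a block, which separates all 1 ng/L arrays from the controls, and 7 with the slide as a block. The median change at 1 ng/L of the 981 probes called at 100 ng/L, in their direction, was 1.52 within the slide that held 1 array of 1 ng/L and 0.99 within the slide that held 2. The authors' deposited values, taken as they stand, called 2112 probes higher and 100 lower at 1 ng/L. Normalized again over all arrays, an alternative chosen after seeing the data, they called 171 higher and 231 lower.

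At 10 ng/L 0 probes were called against the control by limma, and 902 had an unadjusted p under 0.05. With changes of known size simulated in 200 probes, the same fit recovered 34 of 66 at a log2 change of 3, 9 of 67 at 2 and 0 of 67 at 1 in this comparison. At a log2 change of 1 it also recovered 0 of 67 in the comparisons of 3 fish with 3. The probes called at 100 ng/L had medians of 0.21 (the higher ones) and -0.13 (the lower ones) on the log2 scale at 10 ng/L. Probe UF_Ppr_AF_105439 stood at 12.26 ± 0.74 (SD, n = 2) and UF_Ppr_AF_107820 at 7.74 ± 0.74 (SD, n = 2), while UF_Ppr_AF_104891 stood at 12.47 ± 3.07 (SD, n = 2), with a log2 change of 6.27 ± 1.71 (SE, limma adjusted p = 0.603). The changes at 10 and 100 ng/L gave r = 0.266 across probes, against 0.446 for simulated unchanged groups, and a covariance of 0.262 against 0.242, a difference of 0.0200. In that simulation the 100 ng/L group was unchanged too. Changes at 100 ng/L alone would lower r, so the simulated r is no benchmark here. With separate controls in the same 6 ways, r was -0.0681 to 0.218. Without DES 10 ng/L replicate 4 the count was 17, and without DES 10 ng/L replicate 3 it was 3. In those fits the single fish left was assumed to vary like the other groups. The median change of the 981 probes in their direction was 0.42 and -0.04 within the 2 slides that held both a 10 ng/L and a control array.

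**Figure D3:**
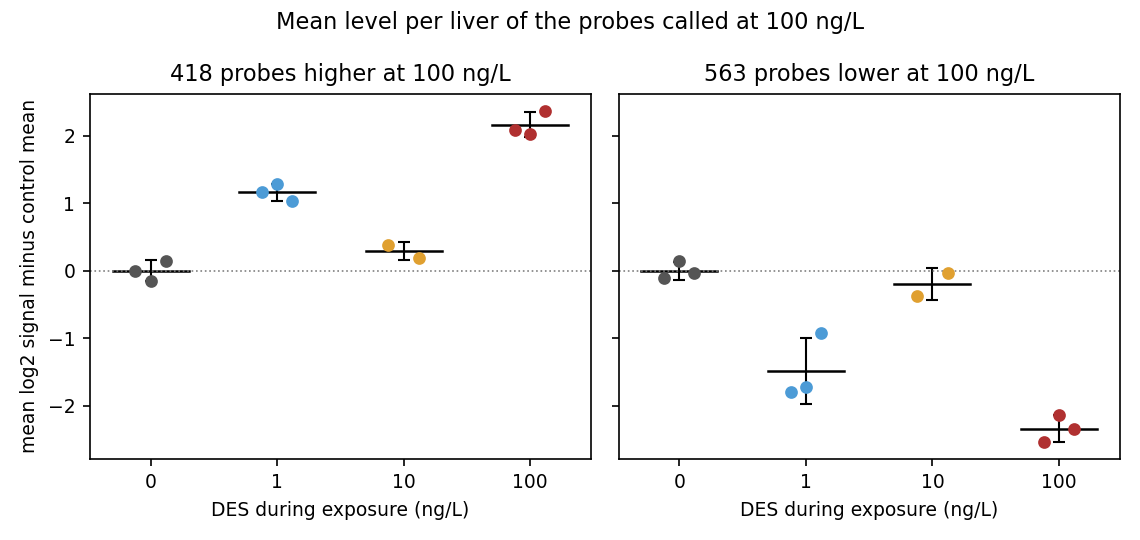
Each point is the mean, for one liver, of the normalized log2 signal minus the control mean over the 418 probes called higher (left) and the 563 called lower (right) at 100 ng/L, with group means and SD bars. The 1 ng/L livers lay between 1.03 and 1.28 for the higher probes and the 10 ng/L livers at 0.19 and 0.38; the probes were selected on the 100 ng/L and control arrays.

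Between concentrations, the 100 ng/L livers differed from the 10 ng/L livers in 543 probes by limma, 223 higher and 320 lower. Probe UF_Ppr_AF_105439 fell by 7.29 ± 1.07 (SE, limma adjusted p = 0.0173) and UF_Ppr_AF_112224 rose by 5.04 ± 1.00 (SE, limma adjusted p = 0.0283) in this comparison. For UF_Ppr_AF_112224, 2 of 3 spots at 100 ng/L were saturated, where the signal is a lower limit. The count was 2 with the slide as a block and 5 with the tank number as a block. It was 7 without DES 10 ng/L replicate 3, 38 without DES 10 ng/L replicate 4 and 4 without DES 100 ng/L replicate 5. It was 303 without control replicate 4, 297 without control replicate 5, 233 without DES 100 ng/L replicate 1 (for this comparison the same fit as the spike-in level as a block) and 285 without DES 100 ng/L replicate 4. The 75th percentile scaling called 259 higher and 245 lower, and the authors' deposited values called 1186 higher and 344 lower. Normalized again over all arrays, an alternative chosen after seeing the data, the deposited values called 438 higher and 558 lower.

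The 100 ng/L livers differed from the 1 ng/L livers in 4 probes, 2 higher and 2 lower, and 1457 had an unadjusted p under 0.05. None of the 4 probes given by identifier was among them (limma adjusted p = 0.201 to 0.944) or among the calls of 10 against 1 ng/L (0.125 to 0.372). The 10 ng/L livers differed from the 1 ng/L livers in 7 probes, 4 higher and 3 lower, with 1760 at an unadjusted p under 0.05. Among the 981 probes called at 100 ng/L, 91.8% had opposite signs in the comparison of 10 with 1 ng/L and in that of 100 ng/L with control, and over all probes r was -0.453. These comparisons share 0 arrays, and probes are not independent replicates. Leaving out single arrays gave 0 to 2 probes for 100 against 1 ng/L, except 3 without control replicate 2. For 10 against 1 ng/L it gave 32 without DES 10 ng/L replicate 4, 21 without DES 1 ng/L replicate 6, 4 without control replicate 2, and 3 without control replicate 4 or 5, DES 1 ng/L replicate 4 or any array of 100 ng/L. The authors' deposited values gave 109 higher and 2176 lower for 100 against 1 ng/L, and 48 higher and 3515 lower for 10 against 1 ng/L. Normalized again over all arrays, an alternative chosen after seeing the data, those values gave 36 higher and 6 lower, and 90 higher and 34 lower.

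Taking all 4 groups together, 440 probes differed among groups by limma's F-test at an adjusted p under 0.05. With the slide as a block it called 41, with the spike-in level as a block 272, and with the tank number as a block 8. Without DES 100 ng/L replicate 5 the count was 7, without control replicate 4 it was 10, and without control replicate 5 it was 98. It was 222 without control replicate 2, 239 without DES 1 ng/L replicate 4, 254 and 275 without DES 10 ng/L replicates 3 and 4, and 131 and 239 without DES 100 ng/L replicates 1 and 4. The slope on log10(concentration + 1) called 0 probes, with 1817 at an unadjusted p under 0.05 and a lowest adjusted p of 0.109, and 1 without DES 100 ng/L replicate 4. In simulated data the same fit recovered 47 of 100 probes with a slope of 1 and 75 of 100 with a slope of 1.5. The simulated probes followed the slope apart from the spread within groups. On the 981 probes called at 100 ng/L, the 1 ng/L livers shifted by 58.7% of the 100 ng/L shift and the 10 ng/L livers by 10.9%. Such departures from a slope add to its residual, so the simulated shares can overstate what the fit recovers here.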

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

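Chosen after the results had been seen were the tests of the spike-in groups, the slide, the table's normalization, array brightness, esr1 mRNA and regroupings within slides, but not those of other splits of the arrays.

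The spike-in control probes, which no comparison uses, read 11.21 (mean log2 processed signal) on DES 100 ng/L replicate 1, above the highest control array at 10.62, and so stood out as a signal outside the main measurement. The 3 control arrays and this array lay at 10.26 or more and the other 7 arrays at 8.81 or less. No control array shares the lower level, so the spike-in level and exposure are largely confounded.

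The first pattern weighed is the 981 probes called at 100 ng/L. The grouping of arrays by spike-in level rests on the spike-in signal alone, and whether their labelling differed is not known. If what set the spike-in levels apart had caused these calls, arrays at the level of DES 100 ng/L replicates 4 and 5 (8.45 and 8.52) would have shifted. The 1 ng/L arrays lay at that level (8.22 to 8.81) and shifted by 58.7% of the mean shift at 100 ng/L on these probes. The 10 ng/L arrays shifted by 10.9% but lay lower (7.50 and 7.58), so they cannot decide the question. DES 100 ng/L replicate 1, with control-like spike-ins, reached 84.4% of the shift of the other 100 ng/L arrays on 442 probes called without it. Its score and the choice of those probes used the same controls, so the score is not fully independent. The spike-in level as a block, which leaves that array alone against the controls, adds no separate evidence. With the slide as a block 97.9% of the median change remained, on probes selected for their change without it, and 448 of the tested probes were called. An offset between slides is thus argued against as the whole cause, but the share that remained is not independent of that selection. Only DES 100 ng/L replicate 1 argues against the spike-in grouping as the cause, which therefore stays open. Of the 10 splits of these 6 arrays, fitted alone, 1 (the real one) gave as many as its 769 probes and the highest other gave 1; 10 splits are too few for a share under 0.05, so DES remains a hypothesis here.

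The second pattern is that on these probes the livers of 1 ng/L shifted by 58.7% of the shift at 100 ng/L and those of 10 ng/L by 10.9%. Low brightness of the 10 ng/L arrays is argued against, since DES 10 ng/L replicate 4 (75th percentile of signal 480) was brighter than all controls and shifted less than the dim replicate 3 (0.115 against 0.377), and among the 436 called probes that lay in the 3143 brightest tested the median shift at 10 ng/L was 8.80% of that at 1 ng/L. The spike-in level of the arrays stays open, because the 10 ng/L arrays (7.50 and 7.58) lay below all those of 1 ng/L (8.22 to 8.81), and a wrong label was not tested. Whether liver expression followed the fish's esr1 mRNA rather than the concentration also stays open: over the 5 fish of both groups, the slopes on log10 esr1 mRNA correlated with the change at 100 ng/L at r = -0.476 across 12552 probes, as low in 3 of 120 orders (exact one-sided permutation p = 0.025; r = -0.268 within concentrations, the lowest of 12 orders, exact one-sided permutation p = 0.0833, the smallest possible). DES 10 ng/L replicate 3 had lower esr1 mRNA than DES 1 ng/L replicate 6 (199 against 215) but a smaller shift (0.377 against 0.977), and since esr1 mRNA differed between the 2 groups this test largely repeats their difference.

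The third pattern is that 95.5% of the 2212 probes called at 1 ng/L in the authors' deposited table were higher. After the table was normalized over all 11 arrays, 42.5% of 402 calls were higher, close to the 42.1% from the scanner values. That normalization removes a general offset between groups whatever its cause, and the scanner values went through it too. The fall in the share therefore cannot tell explanations apart. A normalization within each treatment group is a candidate explanation, since each column lay within 0.0418 of a loess run within its own group. No biological explanation was tested for the excess.

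For 1 ng/L against control, 2 of the 10 splits of the 6 arrays gave as many probes as the real 3, and the highest other split gave 4. For 100 against 1 ng/L, 3 of the 10 splits gave as many as the real 1, and the highest other gave 1. In both cases 10 splits are too few for a share under 0.05. Of 100 regroupings of all 11 arrays, 1 (the real one) gave as many as the 440 probes of the F-test and the highest other gave 64. Those regroupings did not keep the slides. Of 100 regroupings within slides 1 (the real one) gave as many and the highest other gave 4. With the slide as a block 1 (the real one) gave as many as its 41 probes and the highest other gave 4. No drawn regrouping other than the real one thus reached these counts, but not all possible ones were drawn. Neither set kept the tank numbers, and with the tank number as a block the F-test called 8 probes.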

How the results depend on the processing

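Added after the data were seen were the spot mean without background subtraction, the table normalized over all arrays, the spike-in level block and the fit without the 2 dimmest arrays. The counts of calls moved by more than 1.5 times under many settings, and the cause was not tested. Of 17 alternatives for 100 ng/L against control 8 stayed within 1.5 times of 981 (range 102 to 1926), and of 17 for 1 ng/L 2 stayed within 1.5 times of 76. Only 6446 probes were well above background on all 11 arrays.

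At 1 ng/L, 75th percentile scaling gave 10 probes, quantile normalization 8, no filter 40 and the 2 groups alone 3. The 2 groups alone gave 1 probe for 100 against 1 ng/L, 41 for 100 against 10 ng/L and 0 for 10 against 1 ng/L. For 100 against 1 ng/L, 75th percentile scaling gave 0, and quantile normalization, no filter and outlier spots kept gave 1 each. For 10 against 1 ng/L, quantile normalization and no filter gave 3 each. Normexp gave 178 at 1 ng/L, 1638 at 100 ng/L, 1018 for 100 against 10 ng/L and 914 over the 4 groups. Probes well above background on all arrays gave 283 at 1 ng/L, 1528 at 100 ng/L, 1079 for 100 against 10 ng/L, 95 for 10 against 1 ng/L, 1 for 100 against 1 ng/L, 1045 over the 4 groups and 1 for the slope.

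The slide as a block gave 7, 448 and 2 probes for 1 ng/L, 100 ng/L and 100 against 10 ng/L, 0 for 100 against 1 ng/L, 4 for 10 against 1 ng/L and 41 over the 4 groups. The intensity trend gave 228 at 1 ng/L, 1022 for 100 against 10 ng/L, 59 for 10 against 1 ng/L, 8 for 100 against 1 ng/L and 950 over the 4 groups. Array weights gave 610 at 1 ng/L, 1926 at 100 ng/L, 309 for 100 against 10 ng/L, 3 for 10 against 1 ng/L, 1301 over the 4 groups and 14 for the slope. The deposited table gave 2212, 1 and 1856 at 1, 10 and 100 ng/L, 2285, 1530 and 3563 for 100 against 1, 100 against 10 and 10 against 1 ng/L, 4283 over the 4 groups and 840 for the slope. Normalized over all arrays it gave 402, 1, 1556, 42, 996, 124, 1043 and 6 in that order. The spot mean gave 340 at 1 ng/L, 69 for 10 against 1 ng/L and 859 over the 4 groups.

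The spike-in level as a block gave 0 at 1 ng/L, 102 at 100 ng/L, 0 for 100 against 1 ng/L, 233 for 100 against 10 ng/L, 3 for 10 against 1 ng/L and 272 over the 4 groups. Between concentrations it is the same fit as without DES 100 ng/L replicate 1. Without the 2 dimmest arrays the counts were 5, 4 and 345 at 1, 10 and 100 ng/L, 0 for 100 against 1 ng/L, 9 for 100 against 10 ng/L and 15 over the 4 groups.

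Fish with the same tank number did not deviate together: of 15 pairs, 2 correlated above 0.1 (range -0.209 to 0.165), and of 8 pairs with the same fish number 2 did (range -0.0931 to 0.183). With the tank number as a replicate block the counts were 4 at 1 ng/L, 481 at 100 ng/L, 1 for 100 against 1 ng/L, 5 for 100 against 10 ng/L, 1 for 10 against 1 ng/L and 8 over the 4 groups. The fish number as a random replicate block gave 11 for 10 against 1 ng/L, and its other counts stayed within 1.5 times.

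Leaving out single arrays gave 2 to 155 probes at 1 ng/L, 0 to 17 at 10 ng/L, 114 to 1047 at 100 ng/L, 0 to 3 for 100 against 1 ng/L, 4 to 600 for 100 against 10 ng/L, 3 to 32 for 10 against 1 ng/L, 7 to 582 over the 4 groups and 0 to 1 for the slope. The 4 probes given by identifier kept their direction at 100 ng/L in every setting that tested them. UF_Ppr_AF_107820 missed the threshold in 6 of 27 settings, UF_Ppr_AF_104891 in 2 of 27, and UF_Ppr_AF_112224 and UF_Ppr_AF_105439 in 1 of 28 each, with the spike-in level as a block among them for all 4. Their log2 changes were -7.79 to -3.46, 7.10 to 9.94, 6.06 to 6.83 and -7.35 to -5.05 in that order.

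Among the endpoints, plasma vitellogenin kept its call in all 13 settings, with an adjusted p of 0.00208 to 0.0453. The rank of concentration took the gonadosomatic index past the threshold (r = -0.758), and the linear scale took testosterone to r = -0.680 (adjusted p = 0.0588) and ex vivo oestradiol to r = -0.00346. Leaving out single fish gave r of -0.889 to -0.482 for vtg mRNA, -0.824 to -0.545 for esr1 mRNA, -0.734 to -0.610 for the gonadosomatic index, -0.0440 to 0.280 for ex vivo oestradiol, -0.809 to -0.678 for testosterone and -0.0569 to 0.424 for weight. The gene list tests, named genes and the comparison of array signal with vtg and esr1 mRNA were not run, since 0 probes carry a gene name.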

Other observations

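The relations and groupings in this part were all chosen after the data had been seen. With the 8 treated fish as 1 group, every fish had a lower gonadosomatic index than every control (3.41% ± 1.84, SD, n = 8, against 9.92% ± 3.19, SD, n = 3), with an exact two-sided permutation p of 0.00606, the smallest that 165 splits can give, and an adjusted p of 0.0485 over 8 endpoints. For vtg mRNA 7 of the 8 treated fish lay below all controls (exact permutation p = 0.0545, adjusted p = 0.162), and for esr1 mRNA 7 lay below and 1 above (exact permutation p = 0.0606, adjusted p = 0.162).

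Among the 8 fish outside the 100 ng/L group, liver vtg mRNA and esr1 mRNA rose together on log10 scales (r = 0.896, exact permutation p = 0.0198, adjusted p = 0.0595 over 3 relations; rho = 0.833, exact permutation p = 0.0154, adjusted p = 0.0461). Without the 2 fish farthest from the median esr1 mRNA r was 0.448 (exact permutation p = 0.397, n = 6), so the relation rested on those fish. Plasma vitellogenin showed no such relation with vtg mRNA (r = -0.200, exact permutation p = 0.831, adjusted p = 0.831; rho = -0.333, exact permutation p = 0.428, adjusted p = 0.428) or with esr1 mRNA (r = -0.469, exact permutation p = 0.246, adjusted p = 0.369; rho = -0.595, exact permutation p = 0.132, adjusted p = 0.198). Without the 2 farthest fish these were -0.555 and -0.521. In the 100 ng/L fish the highest plasma vitellogenin of the 11 fish stood beside vtg mRNA below every control.

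Across all 11 fish, limma slopes on log10 esr1 mRNA called 1360 probes, 815 of them higher where esr1 mRNA was higher. Slopes on log10 vtg mRNA called 164 probes and on log10 plasma vitellogenin 432. Slopes on the gonadosomatic index, plasma oestradiol, ex vivo oestradiol, ex vivo testosterone and body weight (each on a log10 scale) called 0, with 715, 239, 302, 924 and 331 probes at an unadjusted p under 0.05. Without the 100 ng/L fish the calls were 0 for esr1 mRNA, 6 for vtg mRNA and 0 for plasma vitellogenin, with 1619, 1070 and 660 at an unadjusted p under 0.05, and with one mean per group in the model they were 0 for all 8 endpoints. Leaving out instead each of the 56 sets of 3 other fish called 3 to 1443 probes for esr1 mRNA, so the loss of its calls was not matched by any such set. For vtg mRNA 5 of the 56 sets left 6 calls or fewer, and for plasma vitellogenin 33 left 0, so by calls the loss for these endpoints is also what fewer fish can give. By the number of probes at an unadjusted p under 0.05, as few as without the 100 ng/L fish were found in 0 of the 56 sets for esr1 mRNA (lowest 1786), 1 for vtg mRNA and 0 for plasma vitellogenin (lowest 1181).

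On the array 709 contigs carried 2 probes, the second marked by a suffix whose meaning the files do not give. Both probes were tested for 376 contigs, and their log2 changes at 100 ng/L correlated with r = 0.236 across contigs. Both probes were called for 2 contigs, with the same sign, and 1 of the pair for 28, where the other probe had the same sign in 15. For the 42 contigs with both probes well above background on all arrays, the changes gave r = 0.189 and the mean levels r = -0.099. There 1 of the pair was called for 6 contigs, and the other probe had the same sign in 2. Whether the 2 probes of a contig read the same transcript is thus unknown. Calls are reported per probe and not per contig. Among the tested probes, calls at 100 ng/L were 436 of the 3143 brightest and 47 of the 3143 dimmest.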
